A study of Homo sapiens with 4 samples.

How the data were processed

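RNA sequencing of H1 human embryonic stem cells at days 0, 2, 3 and 4 of stepwise differentiation toward blood was analysed, with 1 library per day. Per the labels, the cells were kept in a custom form of mTeSR1 medium, RNA was taken with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name BWA, Bowtie and RSEM and the hg19 assembly. The versions of these tools and the role of each are not given in the sources used here. The design text of the series also speaks of BWA with an analysis of variance, and of TopHat with Cufflinks, so the tools named differ between its parts. Each deposited file lists genes by Entrez ID with an estimated (expected) count, a transcript length in base pairs, and FPKM, per the file headers. The deposited expected count is the unit used for all main results. The deposited FPKM was used for 1 alternative, and the deposited length was not used for any result.

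Gene names came from a RefSeq table of GRCh38.p14, used for names and gene types only. Of 19390 gene IDs listed in any library, 19273 matched it and 117 did not. No coordinates are given. Of all IDs, 15615 were listed in all 4 libraries, and a gene absent from a file was taken as 0 in it. Expected counts were rounded to whole numbers before any ratio or interval. Of the values, 69.5, 69.5, 69.4 and 70.1% were exactly whole as deposited, with a tolerance of 0, at days 0, 2, 3 and 4. Totals were 5.04, 5.20, 5.20 and 5.49 M expected counts, so 1 read is 0.194, 0.196, 0.193 and 0.182 CPM. TMM factors from edgeR 4.0.16 in R 4.3.3 were 1.02, 0.981, 0.995 and 1.00, and CPM were computed on the scaled totals. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

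There are no replicates, so a rule of size took the place of tests. A gene with at least 1 CPM in either library counted as higher or lower where log2(CPM + 1) differed by at least 2, which is 4-fold on that scale. Folds of single genes are ratios of CPM without a pseudocount, with exact 95% intervals from the conditional binomial, and CPM have exact Poisson intervals. Both cover counting error only. For a gene with 0 counts in 1 library the fold is a bound against a floor of 3 counts in that library. The 5 comparisons were day 2 with 0, 3 with 2, 4 with 3, 4 with 2 and 4 with 0. Time-course classes used the same 4-fold threshold, and a gene peaked on the day of its highest value only.

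Before the data were examined, 30 gene lists, the comparisons, the rules and most alternatives were fixed. A list was described by the median log2 ratio of its members with at least 1 CPM in either library, if 3 or more were left. It was called apart where the median lay outside the central 95% of 10000 random lists, drawn from the same 20 bins of mean expression. Members of a list are not independent, and no p-value was attached. A second endoderm list and a list of interferon-stimulated genes were added later, for the closing section. No member of the list of mitochondrial transcripts was analysed here. The list of haemato-endothelial transcription factors is called regulators of early blood and endothelium in the text. Named genes were the 10 largest differences in each direction (5 for the single-day steps) among genes of at least 10 CPM in either library, up to 4 members of each list with the largest difference, and 13 fixed markers: POU5F1, SOX2, NANOG, TBXT, MIXL1, KDR, CD34, CDH5, PECAM1, TAL1, RUNX1, GATA1 and PTPRC.

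The rule and the list call were tested on simulated data with counting error only, around 1 mean per gene. Differences were planted in genes with a mean of at least 5 CPM. Variation between cultures or libraries was not simulated, so the calls give no error rate for the real libraries. Nor do they show how well differences are found in genes of 1 to 5 CPM. Without planted differences, 0 genes were called in each comparison. Of 50 genes with a planted 6-fold increase 49 to 50 were called, of 50 with a 6-fold decrease 38 to 43, of 50 with a 12-fold increase 50, and of 50 with a 2-fold difference 0. Of 5 planted lists of 15 genes 5 were called apart, and of 5 lists without a difference 1 was called apart as well.

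Alternatives changed 1 choice at a time: pseudocounts of 0.1 and 5, median-of-ratios size factors, a common total, no filter, a minimum of 5 CPM, protein-coding genes alone, list medians without the member of largest change, and correlations over genes of at least 10 CPM. The deposited FPKM, a setting without the 102 read-through gene models, and the medians of the 2 later lists without the filter were added after the data were seen. The FPKM setting changed several choices together: it used no TMM factors, and its pseudocount and minimum of 1 were in FPKM, not CPM. A count was called the same within 1.5 times, and a correlation within 0.05. Some genes that can share reads with copies, pseudogenes or read-through models are named as less certain. The marking is not complete, so a gene without it can be affected too.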

Results

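RNA of H1 cells, an established line of human embryonic stem cells, was sequenced on days 0, 2, 3 and 4 of a stepwise differentiation toward blood. The cells received activin A at 40 ng/ml with BMP4 at 50 ng/ml from day 0 to day 2, then VEGF at 40 ng/ml with bFGF at 50 ng/ml from day 2 to day 4. Each day is 1 library, so the series holds 4 libraries without replicates. Differences between days therefore have no replicate check, no p-value is given, and the 95% intervals cover counting error only. The libraries held 5.04, 5.20, 5.20 and 5.49 M expected counts at days 0, 2, 3 and 4, over 17383, 17390, 17562 and 17664 listed genes. A single read was worth 0.182 to 0.196 CPM (counts scaled to library size), and the floor of 3 counts used for genes listed in only 1 of a pair of libraries was 0.545 to 0.588 CPM. The translation elongation gene EEF1A1 led the early libraries, with 0.919% of counts at day 0 and 0.727% at day 2. The extracellular matrix protein fibronectin, FN1, led the later ones, with 1.17% at day 3 and 1.04% at day 4.

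Across 16085 genes, the days lay in order. Pearson's r on log2(CPM + 1) was 0.894 between days 0 and 2, 0.864 between days 0 and 3, and 0.850 between days 0 and 4. It was 0.962 between days 2 and 3, 0.970 between days 3 and 4, and 0.932 between days 2 and 4. Spearman's rho ranged from 0.855 to 0.972 with the same extremes. These are correlations across genes, which are not independent replicates, and no 2 libraries were copies of each other.

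**Figure D1:**
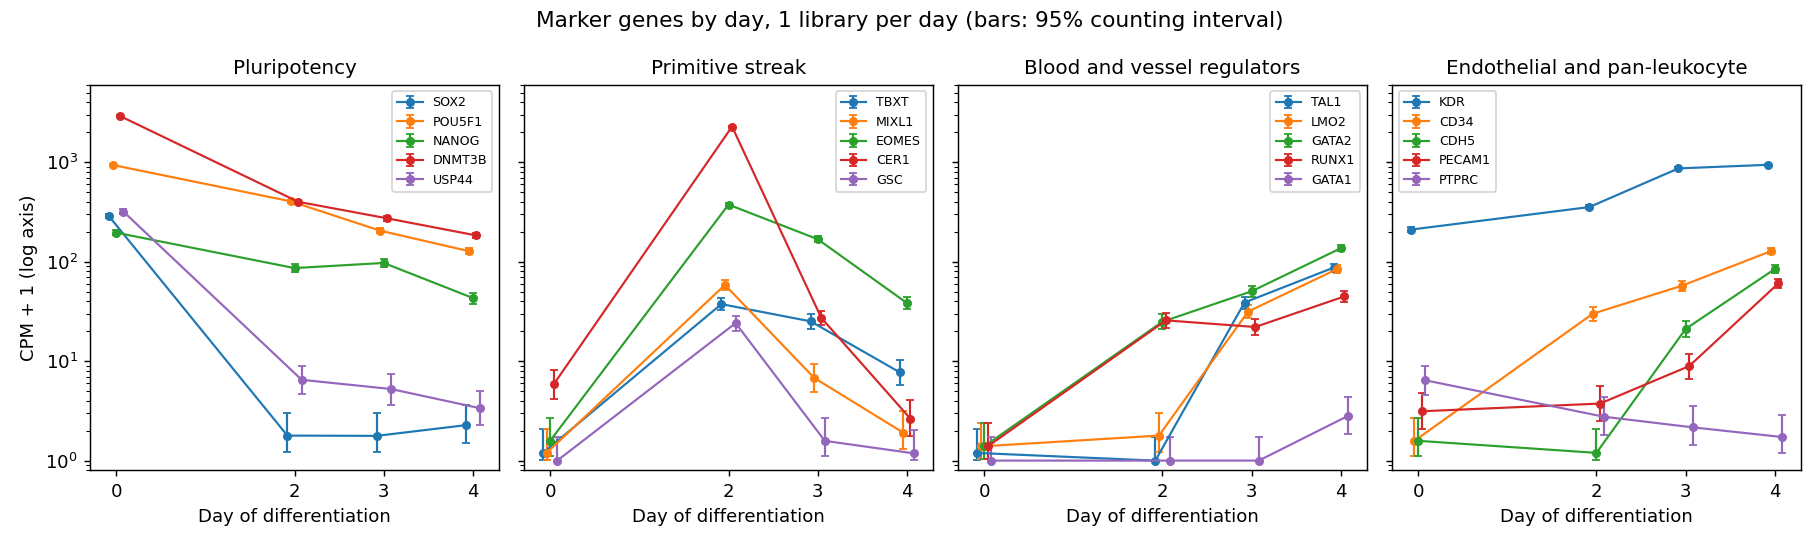
CPM + 1 on a log axis against the day of differentiation for 20 marker genes in 4 groups, with 1 library per day and bars for the 95% counting interval. SOX2 measured 286 CPM at day 0 and 0.785 at day 2, CER1 peaked at 2287 CPM at day 2, and TAL1 reached 86.3 and CDH5 83.4 CPM at day 4.

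The comparison of day 2 with day 0 covers the activin A and BMP4 step. Genes of the undifferentiated state were lower at day 2, and genes of the primitive streak, the structure of the embryo from which mesoderm and endoderm form, were higher. SOX2 (gene ID 6657), a core transcription factor of pluripotent cells, measured 286 CPM at day 0 and 0.785 CPM at day 2, which is 364-fold lower (95% counting interval 142 to 1338). CER1 (gene ID 9350), a secreted antagonist of NODAL and BMP, measured 4.85 and 2287 CPM, 472-fold higher (319 to 729). EOMES (gene ID 8320), a T-box transcription factor of the streak, was 644-fold higher (220 to 3124), at 374 CPM on day 2. Of 15379 genes with at least 1 CPM in either library, 712 were at least 4-fold higher at day 2 and 297 at least 4-fold lower on the log2(CPM + 1) scale.

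Of the 16 pluripotency genes, 10 were at least 2-fold lower and none was 2-fold higher at day 2, with a median log2 ratio of -1.25 against -0.29 to 0.39 in the central 95% of matched random lists. USP44 was 58.1-fold lower (40.0 to 87.7), PRDM14, a regulator of the pluripotent state, 40.3-fold (22.3 to 81.2), and the DNA methyltransferase DNMT3B 7.33-fold (7.0 to 7.68). POU5F1 stood at 940 and 404 CPM, 2.33-fold lower (2.21 to 2.45), and NANOG at 195 and 85.3 CPM, 2.29-fold lower (2.04 to 2.56). Both have processed pseudogenes that can share their reads, so their levels are less certain than their intervals say. Beside these, the largest decreases were in CAMKV, 64.5-fold (27.3 to 199.8), VSNL1, 35.9-fold (22.5 to 60.9), the noncoding RNA D21S2088E, 236-fold (42.0 to 9371), and LMO3, at least 55.7-fold. PHOSPHO2-KLHL23 was at least 78.1-fold lower, NME1-NME2 at least 53.7-fold and CKMT1B at least 44.5-fold. These 3 share sequence with neighbouring or duplicated genes: NME1, NME2 and NME1-NME2 together measured 349.7 and 287 CPM, whereas CKMT1A and CKMT1B together were lower as well, at 51.2 and 7.06 CPM.

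All 15 measured primitive streak genes were at least 2-fold higher at day 2, with a median of 4.58 (4.41 with genes at 0 counts set to their bound) against -0.55 to 0.48 in random lists. MIXL1 measured 0.194 and 57.5 CPM, 296-fold higher (52.8 to 11746), and TBXT, the brachyury gene, 0.194 and 36.5 CPM, 188-fold higher (33.4 to 7471). LHX1 was 269-fold higher (91.9 to 1309). Lateral plate and cardiac mesoderm genes were also higher, 14 of 14 by at least 4-fold, with a median of 4.18 against -0.41 to 0.46. Among them TBX3 was 234-fold higher (107 to 639), the ligand gene BMP4 185-fold (78.9 to 571), HAND1 166-fold (87.0 to 363) and MSX2 174 CPM against 1.16. The 10 largest increases further held ANKRD1, 561-fold (192 to 2725), ALPK2, 504-fold (139 to 4169), the WNT secretion factor WLS, 304-fold (139 to 829), SLCO2A1, 186-fold (94.3 to 433), and RHOBTB3, 160.3-fold (119.7 to 220.0).

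Endoderm genes had a median of 2.76 at day 2 against -0.52 to 0.58 in random lists, with 8 of 11 at least 2-fold higher and 2 at least 2-fold lower. GATA6 was 246-fold higher (95.9 to 906), SOX17 466-fold (83.3 to 18458) and GATA4 188-fold (64.0 to 915). The trophoblast and amnion list had a median of 2.03 (1.70 at the bound) against -0.66 to 0.68 over 8 of 16 members. Of these, 5 were at least 2-fold higher and 1 lower, with GATA3 127-fold (49.2 to 467) and TFAP2A 174-fold higher (47.9 to 1447). The size of this median depends on the filter: it was 0.84 without it and 4.44 at a minimum of 5 CPM. Mesenchymal genes stood at a median of 3.11 against -0.33 to 0.41, 11 of 14 of them at least 4-fold higher. FN1 measured 254 and 3612 CPM, 14.2-fold higher (13.5 to 15.1), the intermediate filament gene VIM 12.5-fold (11.4 to 13.7) and the repressor ZEB2 31.9-fold (18.4 to 60.4). Epithelial genes had a median of -0.63 against -0.31 to 0.39. Their members went both ways: ST14 was 2.72-fold lower (1.98 to 3.80), while the keratin genes KRT8, at 4.69-fold (4.45 to 4.94), and KRT19, at 3.94-fold (3.44 to 4.53), were higher. KRT8 and KRT18 have many pseudogenes, which makes their counts less certain. Basement membrane and matrix genes had a median of 1.11 against -0.26 to 0.37, with COL5A2 27.6-fold (24.9 to 30.7) and COL5A1 26.5-fold higher (22.8 to 31.0), and smooth muscle and fibroblast genes 1.77 against -0.34 to 0.48, with POSTN 58.7-fold higher (41.0 to 87.3) and THY1 3.73-fold lower (3.37 to 4.13).

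Of the targets of the signals added in this step, the BMP list had a median of 3.16 against -0.39 to 0.47, with 11 of 12 members at least 2-fold higher, among them the inhibitory SMAD6, 84.9-fold (44.5 to 186), the BMP antagonist NOG, 258-fold (45.9 to 10228), and BAMBI, 19.3-fold (15.8 to 23.6). Activin and NODAL targets had a median of 1.10 against -0.45 to 0.56, but only 5 of 10 members were at least 2-fold higher, with LEFTY2 15.7-fold (9.77 to 26.9) and LEFTY1 7.20-fold higher (4.76 to 11.3). INHBA, named here after its value was seen, was at least 3.95-fold lower, and the other 4 members differed by less than 2-fold on the log2(CPM + 1) scale. That list lay inside the random range, at 0.58, without its member of largest change. The remaining lists here belong to signals that are not among the factors given for this step. WNT targets had a median of 2.59 against -0.45 to 0.47. Of these, LGR5 was 274-fold higher (93.5 to 1332), LEF1 47.4-fold (21.5 to 130.2), and the WNT antagonist DKK1 at least 66.8-fold. The FGF and ERK target list, at 0.30 against -0.28 to 0.37, and the NOTCH pathway list, with a median of 0.08 and a mean of -0.16 against -0.44 to 0.51, were not apart from random lists.

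Blood and vessel genes divided at day 2. Among regulators of early blood and endothelium, 5 of 10 measured members were at least 2-fold higher and 1 was lower, with a median of 0.97 (0.80 at the bound) against -0.59 to 0.64. The list lay inside the random range at a minimum of 5 CPM. RUNX1 was 63.7-fold higher (17.3 to 532) and GATA2 61.7-fold (16.7 to 515), both needed for the emergence of blood stem cells, whereas ERG was 8.90-fold lower (2.74 to 45.8). TAL1 had 1 count at day 0 and none at day 2, and GATA1 had none at either. The endothelial list was not apart, at 0.29 against -0.39 to 0.42. The apelin receptor gene APLNR was 239-fold higher (149 to 411), CD34 49.9-fold (16.7 to 245) and the VEGF receptor gene KDR 1.69-fold (1.57 to 1.82), while PECAM1 measured 2.13 and 2.75 CPM and CDH5 3 and 1 counts. The endothelial list lay above the random range with a minimum of 5 CPM, at 0.88, and on the deposited FPKM, at 0.64. Blood cell genes were not apart, at 0.03 against -0.75 to 0.53, and the leukocyte gene PTPRC was 3.08-fold lower (1.41 to 7.41).

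Of the remaining lists at day 2, anterior HOX genes (groups 1 to 4) had a median of 3.39 (3.06 at the bound) against -0.90 to 1.30 over 4 measured members, and central and posterior HOX genes (groups 5 to 13) 2.05 (1.39 at the bound) against -0.67 to 0.61 over 10. Both lists were close to 0 counts at day 0, so members passed the filter through day 2 and their direction follows largely from it. The filter left out 8 anterior and 13 central and posterior members. HOXB6 was at least 73.5-fold higher, HOXB9 34.1-fold (13 to 127) and HOXB2 47.0-fold (12.7 to 394). The S phase list was lower, at -0.71 against -0.25 to 0.39, with the helicase gene MCM2 2.23-fold lower (1.99 to 2.51) and MCM5 2.07-fold (1.87 to 2.29). Stress response genes had a median of 0.48 against -0.32 to 0.45, with ASNS 2.71-fold higher (2.47 to 2.98) and HMOX1 5.27-fold lower (4.02 to 7.02), and with a pseudocount of 5 the median was 0.36 and the call ended. Paraxial mesoderm genes had 1.86 against -1.17 to 1.52 over only 3 members, a call that ended without the filter, at 0.26, and at a minimum of 5 CPM. Neuroectoderm (0.39), mitosis (0.13), hypoxia and glycolysis (0.08), cholesterol synthesis (0.32), p53 target (0.23), replication-dependent histone (-0.42) and reference genes (-0.21) were not apart. With a pseudocount of 0.1 the counts of at least 4-fold genes became 1087 higher and 676 lower, and with 5 they became 362 and 112.

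The comparison of day 4 with day 2 covers the VEGF and bFGF step. Regulators of early blood and endothelium and endothelial genes were higher at day 4, the blood cell list was not apart, and streak genes were lower. TAL1 (gene ID 6886), a master regulator of blood formation, went from 0 counts at day 2 to 86.3 CPM at day 4, at least 147-fold higher. CDH5 (gene ID 1003), the endothelial cadherin, had 1 count at day 2 and 83.4 CPM at day 4, 425-fold higher (75.9 to 16833). CER1 went from 2287 to 1.64 CPM, 1398-fold lower (736 to 3058). Of 15406 genes, 357 were at least 4-fold higher and 215 at least 4-fold lower.

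Of 17 measured regulators of early blood and endothelium, 15 were at least 2-fold higher at day 4 than at day 2 and none was lower, with a median of 2.64 (2.46 at the bound) against -0.39 to 0.50. LMO2, a partner of TAL1, was 107-fold higher (41.3 to 393), and the ETS factors ERG and FLI1 were 90.8-fold (30.8 to 443) and 24.6-fold higher (16.5 to 38.3). RUNX1 measured 24.7 and 43.8 CPM, 1.77-fold higher (1.42 to 2.22). GATA1, the erythroid and megakaryocyte factor, was at least 3.09-fold higher, with 1.82 CPM at day 4. The endothelial list had a median of 2.74 (2.47 at the bound) against -0.30 to 0.35, with 21 of 23 members at least 2-fold higher. PLVAP was 721-fold higher (129 to 28507), PECAM1 21.7-fold (12.8 to 40.1), CD34 4.38-fold at 127 against 29.0 CPM, and KDR 2.66-fold at 942 against 354 CPM. The blood cell list was not apart, at 0.14 against -0.48 to 0.65: the erythroid gene RHAG was 7.62-fold higher (3.80 to 17.3), VAV1 at least 7.10-fold and ITGA2B 3.59-fold (1.61 to 9.04), while PTPRC measured 1.77 and 0.727 CPM, a difference within counting error.

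Outside these lists the largest increases were SAMSN1, at least 144-fold, TM4SF1, at least 96.0-fold, SOST, at least 78.1-fold, the endotoxin receptor gene TLR4, 98.7-fold (38.3 to 364), RSPO2, 68.0-fold (35.6 to 149.5), and the collagen gene COL3A1, 82.9-fold (60.3 to 117). The largest decreases after CER1 were SYT4, at least 145-fold, LEFTY1, 99.8-fold (27.3 to 831), TACR1, 64.4-fold (21.7 to 315), MIXL1, 63.2-fold (26.8 to 196), GRP, 62.1-fold (29.9 to 156), and the gene with ID 414216, at least 60.8-fold, which had no match in the name table. ATP12A was 52.8-fold lower (33.6 to 88.2), PPP2R2C 29.7-fold (18.1 to 52.5) and MFAP4 26.9-fold (18.6 to 40.5).

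Primitive streak genes were lower, 13 of 15 by at least 2-fold, with a median of -2.27 against -0.37 to 0.47. EOMES measured 374 and 37.4 CPM, GSC was 127-fold lower (22.4 to 5073), and TBXT measured 36.5 and 6.72 CPM. Activin and NODAL targets had a median of -1.52 against -0.42 to 0.38, with NODAL itself 28.1-fold lower (9.25 to 139). Pluripotency genes had a median of -0.73 against -0.33 to 0.23, with L1TD1 5.97-fold (5.46 to 6.52), TDGF1 5.21-fold (4.82 to 5.63) and POU5F1 3.19-fold lower (2.93 to 3.48). NANOG measured 85.3 and 42.2 CPM, and SOX2, at 0.785 and 1.27 CPM, did not differ beyond counting error. WNT targets had a median of -0.57 against -0.32 to 0.40, with LGR5 3.93-fold lower (3.39 to 4.58) and TNFRSF19 5.78-fold higher (4.34 to 7.83). Neuroectoderm genes had -1.17 against -0.68 to 0.66 over 5 members, with ZIC2 8.03-fold (6.44 to 10.1) and OTX2 4.94-fold lower (3.96 to 6.22), and the median lay inside the random range, at -0.64, without its member of largest change and, at -0.29, without the filter. Epithelial genes had -0.48 against -0.31 to 0.28, with CDH1, the epithelial cadherin, 3.35-fold lower (3.02 to 3.71).

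FGF and ERK targets, at 0.66 against -0.31 to 0.23, were higher, with EGR1 7.30-fold (4.32 to 13.2), SPRY1 4.51-fold (3.61 to 5.70) and CCND1 3.22-fold higher (3.04 to 3.42), and IER3 2.83-fold lower (2.49 to 3.21). The NOTCH pathway list had 0.72 against -0.38 to 0.41, with HEY1 5.38-fold higher (3.53 to 8.50). The endoderm list had a median of 1.97 (1.64 at the bound) against -0.35 to 0.45, with the apolipoprotein genes APOA1, 50.7-fold (25.5 to 118), APOB, 34.0-fold (15.4 to 93.6), and APOA2, 30.9-fold (10.3 to 152), and the fetal plasma protein gene AFP, 16.5-fold higher (7.80 to 42.0). Matrix genes had 0.89 against -0.33 to 0.20, with NID2 35.4-fold (25.3 to 51.0) and COL6A3 13.9-fold higher (10.9 to 18.0) but COL5A2 3.59-fold lower (3.44 to 3.74). Lateral plate and cardiac mesoderm genes had 0.63 against -0.37 to 0.36, with HAND2 13.2-fold higher (8.50 to 21.7). Central and posterior HOX genes had 2.11 (2.06 at the bound) against -0.48 to 0.63, with HOXB8 10.3-fold higher (7.17 to 15.3), and anterior HOX genes 1.75 (1.67 at the bound) against -0.82 to 0.95, with HOXB4 5.27-fold higher (3.08 to 9.61). Without the filter the anterior HOX median was 0.34 and the call ended.

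The paraxial mesoderm list had 1.34 (1.14 at the bound) against -0.76 to 0.96 over 6 members, and reversed to -1.08 at a minimum of 5 CPM, so no direction is given for it. Cholesterol synthesis genes had 0.22 against -0.31 to 0.18, a call that ended on the deposited FPKM. Lists not apart between days 4 and 2 were trophoblast and amnion, with a median of -0.20 and a mean of 0.54, smooth muscle and fibroblast (0.13), mesenchymal (0.12), BMP targets, with a median of -0.06 and a mean of 0.06, S phase (0.11), mitosis (-0.13), hypoxia and glycolysis (0.22), p53 targets (0.27), stress response (-0.21), replication-dependent histones (-0.52) and reference genes (0.13). A pseudocount of 0.1 gave 704 higher and 470 lower genes, and a pseudocount of 5 gave 142 and 82.

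**Figure D2:**
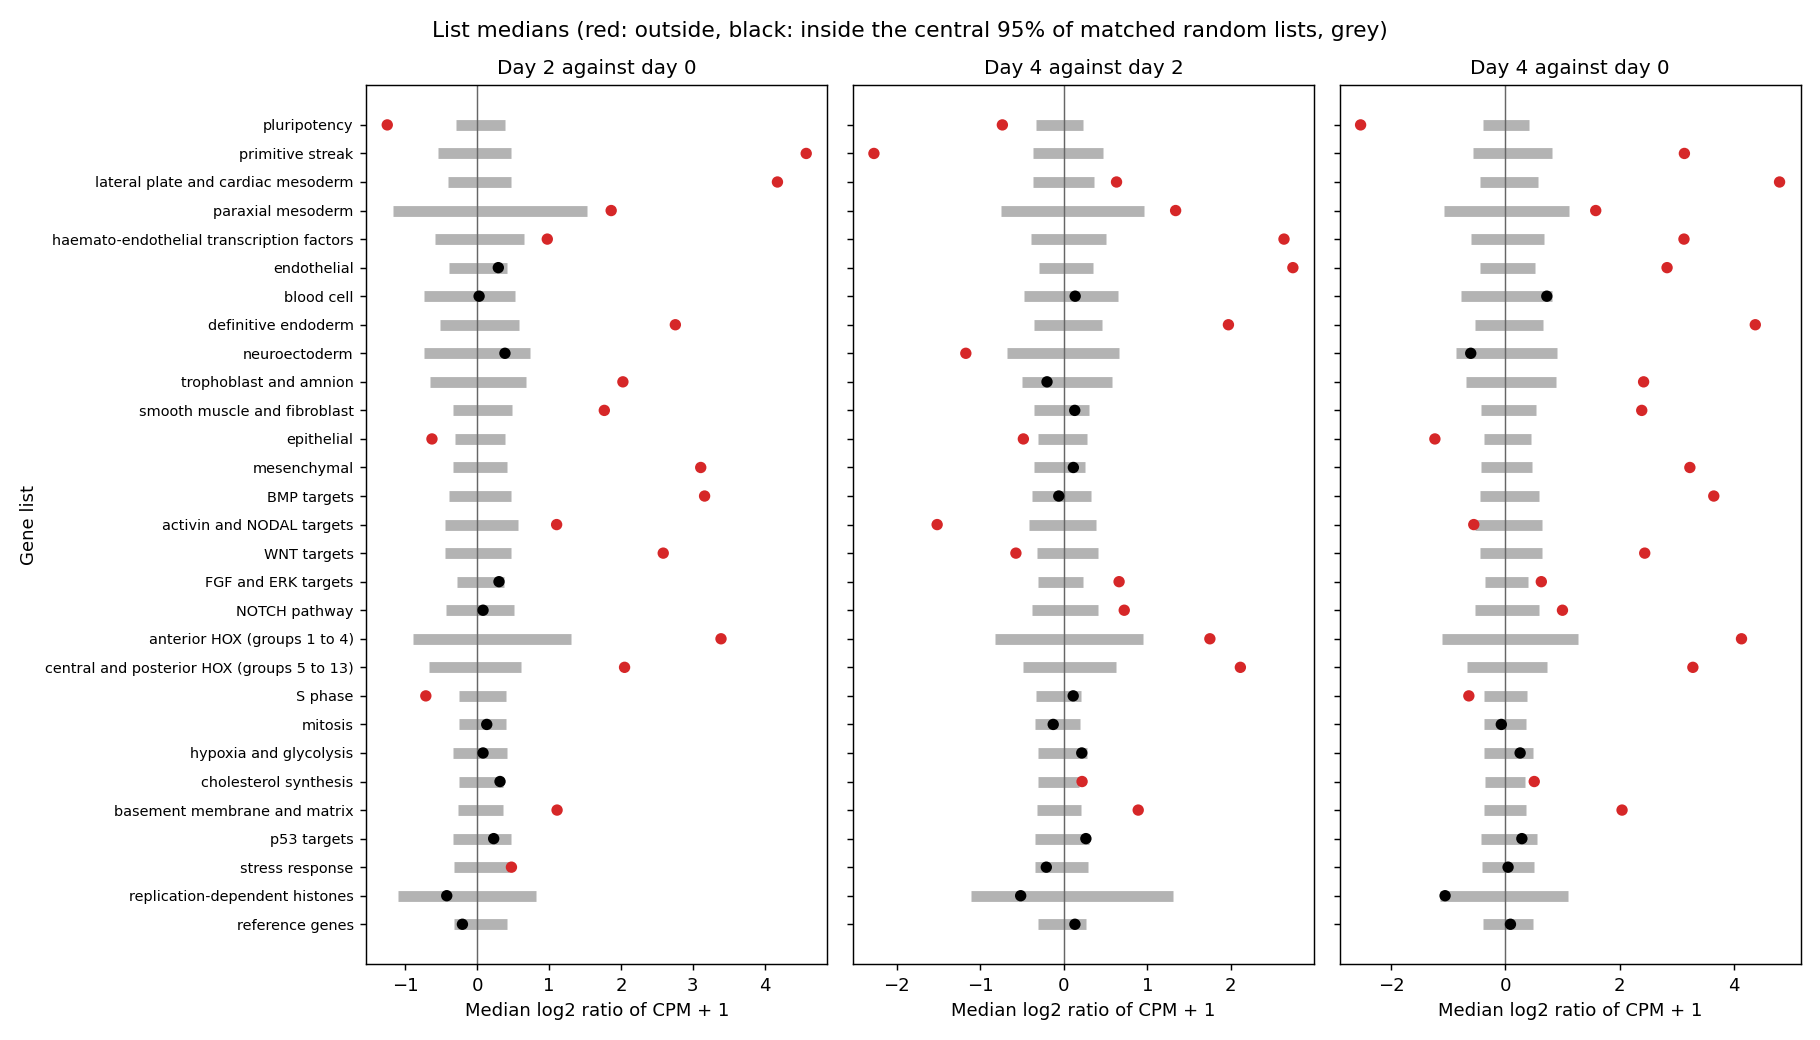
Median log2 ratio of CPM + 1 (points) for each gene list in 3 comparisons, with the central 95% of 10000 matched random lists as grey bars. Points are red where the median lies outside that range, as for regulators of early blood and endothelium at 2.64 and primitive streak at -2.27 between days 4 and 2.

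Day 3 against day 2 gives the first day in VEGF and bFGF. Blood and vessel regulators were already higher: TAL1 at least 64.4-fold, LMO2 38.9-fold (14.9 to 145), ERG 30.5-fold (10.1 to 151) and FLI1 9.62-fold (6.36 to 15.2). CDH5 was 102-fold higher (18.0 to 4085), KDR measured 354 and 868 CPM, and CER1 was 87.0-fold lower (73.5 to 104). Of 15286 genes, 202 were at least 4-fold higher and 62 at least 4-fold lower. The largest increases besides TAL1 were TLR4, 62.1-fold (23.9 to 230), the apelin gene APLN, 63.4-fold (21.4 to 310), EMP1, 50.2-fold (19.3 to 186), and RSPO2, 34.2-fold (17.8 to 75.4). The largest decreases besides CER1 were GSC, 39.9-fold (13.3 to 196), POU2AF1, 24.6-fold (15.9 to 40.0), GRP, 24.1-fold (14.8 to 41.7), and the unmatched gene ID 414216, 172-fold (30.4 to 6815). RUNX1, at 24.7 and 21.1 CPM, and NANOG, at 85.3 and 96.2 CPM, differed little, and GATA1 had no counts on either day.

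Regulators of early blood and endothelium had a median of 1.19 against -0.28 to 0.43 over this day, with 9 of 14 at least 2-fold higher, and endothelial genes 1.41 against -0.21 to 0.28, with 14 of 20 at least 2-fold higher. FGF and ERK targets had 0.97 against -0.19 to 0.16, with EGR1 9.79-fold (5.85 to 17.5), FOS 7.33-fold (3.64 to 16.7) and SPRY1 4.53-fold higher (3.61 to 5.72). Endoderm genes (1.22), paraxial mesoderm (1.17, inside the random range under 4 of the alternatives), anterior HOX (1.44), central and posterior HOX (1.12), matrix (0.68), trophoblast and amnion (0.67), lateral plate and cardiac mesoderm (0.55), NOTCH pathway (0.33), mesenchymal (0.32) and smooth muscle and fibroblast genes (0.28) were also above their random ranges. Of these calls, NOTCH ended with a pseudocount of 0.1 (0.33), without the filter (0.23) and without its member of largest change (0.23), smooth muscle and fibroblast without that member (0.040), and trophoblast and amnion without the filter (0.25). Below them were primitive streak (-0.96), activin and NODAL targets (-1.02), neuroectoderm (-0.91), stress response (-0.36), mitosis (-0.34) and S phase genes (-0.21). LEFTY1 was 20.9-fold lower (10.8 to 46.3), NODAL 11.3-fold (5.24 to 29.1) and the amino acid stress gene ASNS 2.98-fold (2.70 to 3.29). Not apart were pluripotency (-0.11), blood cell (-0.12), epithelial (-0.16), BMP targets (median -0.03, mean 0.10), WNT targets (median -0.06, mean 0.03), hypoxia and glycolysis (-0.08), cholesterol synthesis (0.06), p53 targets (0.18), replication-dependent histones (-0.39) and reference genes (-0.12). The 4-fold counts were 484 and 227 with a pseudocount of 0.1, and 55 and 20 with 5.

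Day 4 against day 3 gives the second day in VEGF and bFGF, with the fewest large differences of the 5 comparisons. Endothelial genes were higher at day 4, led by PLVAP, 12-fold (9.24 to 15.8), PECAM1, 7.52-fold (5.43 to 10.7), and TIE1, 6.94-fold (4.38 to 11.5), and CDH5 measured 20.1 and 83.4 CPM. The blood regulators GFI1B, at least 9.09-fold, CBFA2T3, 4.89-fold (2.46 to 10.8), and KLF1, 4.89-fold (1.85 to 16.3), were higher, RUNX1 measured 21.1 and 43.8 CPM, and GATA1 was at least 3.13-fold higher. Of 15367 genes, 58 were at least 4-fold higher and 35 at least 4-fold lower. Other large increases were COL3A1, 9.25-fold (8.28 to 10.4), the interferon-stimulated gene IFIT1, 10.4-fold (6.77 to 16.7), FCN3, 28.2-fold (7.48 to 238), and the unmatched gene ID 728932, at least 21.6-fold. The largest decreases were CER1, 16.1-fold (8.22 to 35.9), PPIAP46, 12.2-fold (6.58 to 25.0), SHISA3, 6.79-fold (5.10 to 9.19), SERF1A, at least 27.3-fold, and TGIF2-RAB5IF, at least 25.2-fold. PPIAP46 is a transcribed pseudogene, which can share reads with its parent gene, so its level is less certain. The last 2 can share reads with other gene models, so their levels are less certain: SERF1A and SERF1B together measured 24.0 and 25.3 CPM, and TGIF2, RAB5IF and TGIF2-RAB5IF together 111 and 117 CPM.

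Over this day regulators of early blood and endothelium had a median of 1.42 (1.34 at the bound) against -0.36 to 0.34 and endothelial genes 1.30 (1.26 at the bound) against -0.27 to 0.25. Central and posterior HOX (0.49), S phase (0.36) and hypoxia and glycolysis genes (0.28) were above their random ranges. Below them were primitive streak (-1.70), pluripotency (-0.61), WNT targets (-0.60), activin and NODAL targets (-0.44), epithelial (-0.38) and FGF and ERK target genes (-0.26). The activin and NODAL call (-0.31) and the FGF and ERK call (-0.23) ended without the member of largest change. The former also ended with a pseudocount of 5 (-0.26) and at a minimum of 5 CPM (-0.31), the central and posterior HOX call with a pseudocount of 0.1 (0.56), and the hypoxia call on the deposited FPKM (0.27). LHX1 was 4.93-fold lower (4.19 to 5.84), NKD1 2.44-fold (2.10 to 2.84), SPRY4 2.12-fold (1.97 to 2.29) and NANOG 2.28-fold (1.95 to 2.68). Not apart were lateral plate and cardiac mesoderm (median -0.04, mean 0.12), paraxial mesoderm (-0.21), blood cell (median 0.10, mean 0.71), endoderm (0.23), neuroectoderm (-0.37), trophoblast and amnion (-0.20), smooth muscle and fibroblast (0.13), mesenchymal (-0.17), BMP targets (median 0.06, mean -0.04), NOTCH pathway (0.18), anterior HOX (0.09), mitosis (0.15), cholesterol synthesis (0.10), matrix (0.08), p53 targets (0.00), stress response (0.09) and reference genes (0.23). Of 12 measured blood cell genes, 4 were at least 2-fold higher and none was 2-fold lower. That list lay above the random range on the deposited FPKM, at 0.49. The 4-fold counts became 243 and 228 with a pseudocount of 0.1, 11 and 7 with 5, and 77 and 83 on the deposited FPKM, where more genes were lower than higher.

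Day 4 against day 0 covers both steps together. ANKRD1 (gene ID 27063) was 821-fold higher (281 to 3985), HAND1 341-fold (179 to 745), the matrix link protein gene HAPLN1 328-fold (249.7 to 439), at 3304 CPM on day 4, and TAL1 445-fold (79.5 to 17620). SOX2 was 225-fold lower (109 to 559), USP44 135-fold (78.7 to 254) and POU5F1 measured 940 and 126 CPM, 7.43-fold lower. Of 15652 genes, 981 were at least 4-fold higher and 538 at least 4-fold lower. Of the 981, 469 (47.8%) were at least 4-fold higher already at day 2, and of the 538, 217 (40.3%) were at least 4-fold lower already at day 2. Of the 712 genes at least 4-fold higher at day 2, 90 (12.6%) were at least 4-fold lower at day 4 than at day 2. The comparisons set together here share the day 0 or the day 2 library, whose error enters both, and no reference share was computed. The other largest increases were PMP22, 338-fold (144.5 to 1042), CST1, 283-fold (179 to 477), TBX3, 241-fold (111 to 658), APLNR, 219-fold (136 to 376), COL3A1, 199-fold (123 to 349), the growth factor gene IGF2, 166-fold (103 to 285), and PLVAP, 729-fold (130.5 to 28836). The other largest decreases were TMEM132B, 225-fold (96.3 to 695), the kinase gene LCK, 163-fold (44.7 to 1350), RIMS4, 141-fold (38.8 to 1173), ZDHHC22, 112-fold (47.5 to 345), RYR1, at least 108-fold, PTPRZ1, 86.4-fold (61.1 to 127), VSNL1, 53.6-fold (31.1 to 101), and UNC13A, 45.3-fold (32.3 to 65.7).

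Of 17 regulators of early blood and endothelium, 14 were at least 4-fold higher at day 4 than at day 0, with a median of 3.13 (3.10 at the bound) against -0.60 to 0.68. FLI1 was 622-fold higher (111 to 24616), GATA2 350.0-fold (96.6 to 2896), LMO2 216-fold (59.3 to 1785), and RUNX1 measured 0.388 and 43.8 CPM. Endothelial genes had a median of 2.83 against -0.45 to 0.52, 19 of 23 of them at least 4-fold higher, with CD34 219-fold (74.5 to 1063), CDH5 143-fold (48.8 to 698), PECAM1 at 2.13 and 59.6 CPM and KDR at 209 and 942 CPM. Blood cell genes were not apart, at 0.73 against -0.77 to 0.82, although RHAG was at least 23.1-fold higher and LCP1 4.46-fold (3.43 to 5.86). This list was above the random range under both other pseudocounts and without the filter. PTPRC was 7.47-fold lower (2.61 to 29.3), at 5.43 and 0.727 CPM.

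Pluripotency genes had a median of -2.53 against -0.39 to 0.42 between days 4 and 0, with 13 of 16 at least 2-fold lower, including DNMT3B, 16.0-fold (15 to 17.1), and NANOG, at 195 and 42.2 CPM. Lateral plate and cardiac mesoderm genes had 4.80 against -0.45 to 0.56, all 15 at least 4-fold higher, with MSX1 271-fold (74.6 to 2242). The primitive streak list had 3.13 (2.70 at the bound) against -0.56 to 0.81 over 9 measured members. Of these, 7 were at least 2-fold higher and 1 lower, with EOMES 64.4-fold higher (21.7 to 315) and TBXT at 0.194 and 6.72 CPM. The filter left out 7 streak members, among them MIXL1, at 1 and 5 counts. Streak members close to 0 at day 0 passed the filter only through day 4, so their direction follows largely from it. Without the filter the streak median was 1.56. Endoderm genes had 4.37 (3.85 at the bound) against -0.54 to 0.66, with 13 of 14 at least 4-fold higher, led by APOA1, at least 137-fold, SOX17, 285-fold (50.8 to 11290), and GATA4, 216-fold (73.7 to 1051). Matrix genes had 2.04 against -0.37 to 0.35, all 16 at least 2-fold higher, with COL5A1 45.1-fold (38.8 to 52.6) and COL4A2 12.1-fold (11 to 13.2). Mesenchymal genes had 3.23 against -0.43 to 0.46, with CDH11 64.2-fold (47.2 to 89.6), FN1 41.0-fold (38.9 to 43.4) and VIM 39.6-fold (36.2 to 43.5). Epithelial genes had -1.23 against -0.37 to 0.44, with CDH1 5.18-fold (4.70 to 5.72) and ESRP1 5.12-fold lower (4.51 to 5.81), but KRT8 7.71-fold (7.34 to 8.11) and KRT19 6.53-fold higher (5.74 to 7.46).

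Smooth muscle and fibroblast genes had a median of 2.39 against -0.43 to 0.53, with LUM 156-fold higher (53.1 to 760.0). Trophoblast and amnion genes had 2.42 (2.11 at the bound) against -0.70 to 0.88 over 8 of 16 members, and 1.10 without the filter. Among them, GATA3 was 110.1-fold (42.7 to 406) and CDX2 at least 52.8-fold higher. BMP targets had 3.65 against -0.45 to 0.58, with GREM1 128-fold higher (35.1 to 1062), WNT targets 2.44 against -0.45 to 0.65, with LEF1 121-fold higher (55.5 to 332), FGF and ERK targets 0.63 against -0.36 to 0.40, with DUSP4 9.73-fold higher (6.83 to 14.3), and the NOTCH pathway 1.0 (0.98 at the bound) against -0.53 to 0.60, with HEY1 28.3-fold higher (11.9 to 88.4) and NRARP 8.92-fold lower (5.72 to 14.6). At a minimum of 5 CPM the NOTCH median was 0.43 and the call ended. Activin and NODAL targets had a median of -0.55 but a mean of 0.03 against -0.53 to 0.64, with NODAL 18.1-fold lower (5.87 to 90.9), and lay inside the random range on the deposited FPKM. Paraxial mesoderm genes had 1.58 (1.05 at the bound) against -1.07 to 1.12, and the call ended on the deposited FPKM, at 0.23. The value at the bound lies inside that range, but the random lists were drawn without the bound, so no call was made there. S phase genes had -0.64 against -0.37 to 0.38, with CCNE1 2.23-fold lower (1.82 to 2.74) and TYMS 2.02-fold higher (1.81 to 2.27), and cholesterol synthesis genes 0.51 against -0.35 to 0.34, with FDPS 2.00-fold higher (1.86 to 2.15). Neuroectoderm (-0.61), mitosis (median -0.07, mean 0.09), hypoxia and glycolysis (0.26), p53 targets (0.29), stress response (0.05), replication-dependent histones (-1.05, and -0.74 at the bound) and reference genes (0.09) were not apart. The 4-fold counts were 1492 and 930 with a pseudocount of 0.1, and 504 and 223 with 5.

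HOX genes were close to 0 counts at day 0, and most members measured were higher at day 4 than at day 2. Anterior HOX genes had a median of 4.13 (3.47 at the bound) against -1.12 to 1.27 between days 4 and 0 over 5 members, and central and posterior HOX genes 3.28 (2.62 at the bound) against -0.67 to 0.73 over 13, of which 12 were at least 4-fold higher. With day 0 close to 0, members passed the filter of 1 CPM through day 4, so their direction follows largely from it. The filter left out 7 anterior and 10 central and posterior members. Without it the anterior median was 0.79, and that of the other list was lower as well. The HOXB cluster held the highest values: HOXB9 measured 0.776, 26.5, 83.5 and 134 CPM at days 0, 2, 3 and 4, HOXB6 0, 42.8, 94.3 and 114 CPM, and HOXB8 0, 6.28, 39.8 and 64.7 CPM. HOXC8 had no counts at days 0 and 2 and 6.54 CPM at day 4.

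**Figure D3:**
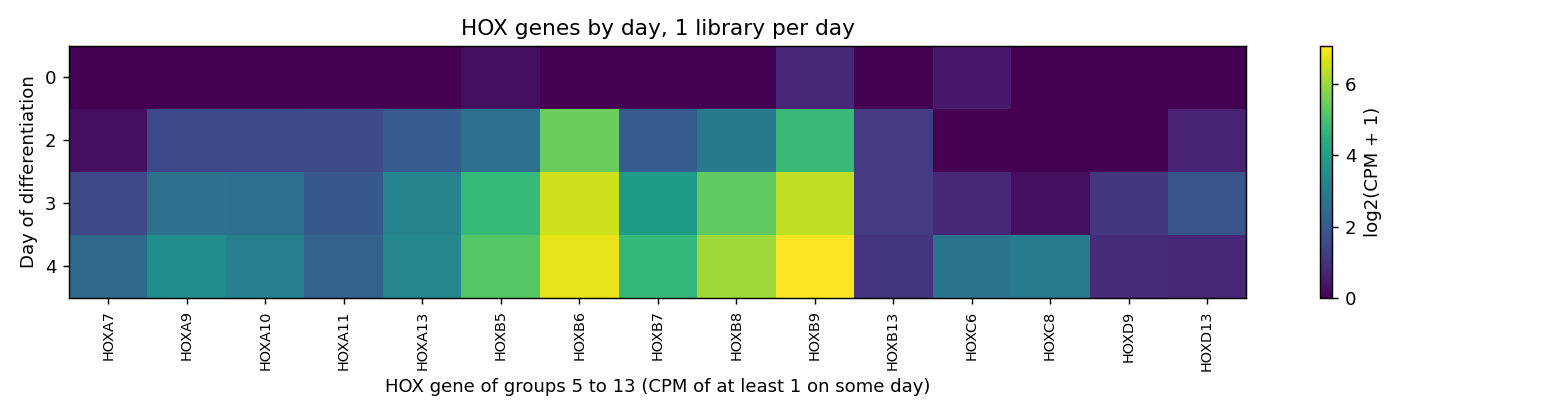
Heat map of log2(CPM + 1) for HOX genes of groups 5 to 13 that reached 1 CPM on some day, with days as 4 lines and 1 library per day. HOXB9, at 134 CPM, and HOXB6, at 114 CPM, are the brightest at day 4, and the day 0 line is close to 0 throughout.

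Genes were also sorted by the shape of their course, and the examples here were chosen after their values were seen. At day 2, 88 genes peaked, which means that the day held their highest value, of at least 1 CPM, at least 4-fold above both day 0 and day 4, and 12 of them were in the fixed lists. Those 12 held 9 streak genes such as MESP1, FGF8 and FGF17, along with LEFTY1, LEFTY2 and POSTN. At day 3, 11 genes peaked, with SHISA6 at 87.4 CPM, APLN at 37.3 CPM and LHX1 at 157 CPM, the same as at day 2, among them. The 11 also held SERF1A and PPIAP46, which can share reads with other genes and are less certain. SERF1A and SERF1B together measured 41.5, 22.2, 24.0 and 25.3 CPM at days 0, 2, 3 and 4, without a peak at day 3. Another 501 genes did not decrease on any day and ended at least 4-fold higher, 73 of them in the fixed lists. CST1, for example, measured 3.49, 46.9, 578 and 986 CPM, IGF2 3.30, 23.3, 272 and 547 CPM, and VIM 91.1, 1138, 2462 and 3614 CPM. A further 333 genes did not increase on any day and ended at least 4-fold lower, 14 of them in the fixed lists, with PTPRZ1 at 503, 18.0, 16.2 and 5.82 CPM and CDH1 at 464, 300, 166 and 89.6 CPM. Over all 5 comparisons, 86 of 144 medians of a list in a comparison lay outside the central 95% of random lists.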

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

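No paired analysis was possible because each day has 1 library, and no library could be left out in turn for the same reason. The alternatives were planned, except the deposited FPKM, the setting without read-through gene models, and the medians of the 2 later lists without the filter, which were chosen after seeing the data. Of the 86 list medians outside the range of random lists, 67 were outside it on the same side under every alternative that gave a value, and 19 fell inside it under at least 1. None turned to the other side of the range, and 14 others came to lie outside it under at least 1 alternative. Median-of-ratios size factors and a common total changed no such call, left every count within 1.5 times, and moved 1 named gene's ratio beyond its counting interval. No scaling shifted the median of all genes by more than 0.06. The minimum of 5 CPM gave a value for 140 of 144 medians and the loss of 1 member for 141, since fewer than 3 members were left in the others. Depth limits low genes: 1 read is 0.182 to 0.196 CPM, and the pseudocount decides the ratios of genes near that level.

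The counts of genes at least 4-fold higher and lower moved under both pseudocounts. With 0.1 they were 1087 and 676 (day 2 to 0), 484 and 227 (day 3 to 2), 243 and 228 (day 4 to 3), 704 and 470 (day 4 to 2), and 1492 and 930 (day 4 to 0), where day 2 to 0 stands for day 2 against day 0. With 5 they were 362 and 112, 55 and 20, 11 and 7, 142 and 82, and 504 and 223 in the same order. On the deposited FPKM the lower genes between days 4 and 3 numbered 83 against 35, and 48.1% of the genes past 4-fold were higher, against 62.4% on the counts. Between days 3 and 2 that share was 65.3% against 76.5%. The other counts stayed within 1.5 times on FPKM, with a minimum of 5 CPM, with protein-coding genes alone and without read-through models. Leaving the filter out cannot alter these counts by construction. With a pseudocount of 0.1, 155 genes peaked at day 2 (88 with 1), 70 at day 3 (11) and 533 were lower stepwise (333). With 5 these were 35, 4 and 158, and 276 were higher stepwise (501). Over genes of at least 10 CPM, Pearson's r was 0.806 between days 0 and 2 (0.894 over all), 0.748 between days 0 and 3 (0.864), 0.723 between days 0 and 4 (0.850) and 0.876 between days 2 and 4 (0.932). Low genes weigh less in that set by construction, and for FPKM the cause was not tested. Of the named genes' ratios, 171 moved with a pseudocount of 0.1 and 201 with 5, and none reversed.

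With a pseudocount of 0.1 in place of 1, these list medians (log2) moved, each given beside its value with a pseudocount of 1. Primitive streak gave 6.55 against 4.58 (day 2 to 0), -3.32 against -2.27 (day 4 to 2) and 4.54 against 3.13 (day 4 to 0). Lateral plate and cardiac mesoderm gave 5.58 against 4.18 (day 2 to 0) and 6.39 against 4.80 (day 4 to 0). Paraxial mesoderm gave 3.45 against 1.58 (day 4 to 0). Haemato-endothelial factors gave 1.83 against 0.97 (day 2 to 0), 1.60 against 1.19 (day 3 to 2), 3.31 against 2.64 (day 4 to 2) and 5.16 against 3.13 (day 4 to 0). Endothelial gave 1.66 against 1.30 (day 4 to 3), 3.28 against 2.74 (day 4 to 2) and 3.96 against 2.83 (day 4 to 0). Blood cell gave 1.29 against 0.73 (day 4 to 0, now apart). Definitive endoderm gave 4.50 against 2.76 (day 2 to 0), 2.44 against 1.97 (day 4 to 2) and 6.39 against 4.37 (day 4 to 0). Trophoblast and amnion gave 3.23 against 2.03 (day 2 to 0) and 4.06 against 2.42 (day 4 to 0). BMP targets gave 3.86 against 3.16 (day 2 to 0). WNT targets gave 3.97 against 2.59 (day 2 to 0) and 3.42 against 2.44 (day 4 to 0). NOTCH pathway gave 0.33 against 0.33 (day 3 to 2, no longer apart). Anterior HOX gave 5.12 against 3.39 (day 2 to 0) and 6.95 against 4.13 (day 4 to 0). HOX groups 5 to 13 gave 4.71 against 2.05 (day 2 to 0), 1.65 against 1.12 (day 3 to 2), 0.56 against 0.49 (day 4 to 3, no longer apart) and 6.46 against 3.28 (day 4 to 0). Replication-dependent histones gave -2.16 against -1.05 (day 4 to 0, now apart). By construction a smaller pseudocount widens the ratios of low genes, and apart from that the cause was not tested.

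With a pseudocount of 5, the medians that moved were as follows. Primitive streak gave 2.63 against 4.58 (day 2 to 0), -0.51 against -0.96 (day 3 to 2), -1.24 against -1.70 (day 4 to 3), -1.46 against -2.27 (day 4 to 2) and 1.51 against 3.13 (day 4 to 0). Lateral plate and cardiac mesoderm gave 2.63 against 4.18 (day 2 to 0) and 3.08 against 4.80 (day 4 to 0). Paraxial mesoderm gave 0.40 against 1.17 (day 3 to 2). Haemato-endothelial factors gave 0.81 against 1.19 (day 3 to 2), 1.04 against 1.42 (day 4 to 3), 1.37 against 2.64 (day 4 to 2) and 1.81 against 3.13 (day 4 to 0). Endothelial gave 0.99 against 1.41 (day 3 to 2), 0.97 against 1.30 (day 4 to 3), 1.96 against 2.74 (day 4 to 2) and 2.14 against 2.83 (day 4 to 0). Blood cell gave 0.36 against 0.73 (day 4 to 0, now apart). Definitive endoderm gave 1.22 against 2.76 (day 2 to 0), 0.88 against 1.22 (day 3 to 2), 0.97 against 1.97 (day 4 to 2) and 2.38 against 4.37 (day 4 to 0). Trophoblast and amnion gave 0.74 against 2.03 (day 2 to 0) and 1.61 against 2.42 (day 4 to 0). BMP targets gave 2.31 against 3.16 (day 2 to 0) and 2.74 against 3.65 (day 4 to 0). NODAL and activin targets gave -0.26 against -0.44 (day 4 to 3, no longer apart). WNT targets gave 1.75 against 2.59 (day 2 to 0) and 1.58 against 2.44 (day 4 to 0). Anterior HOX gave 1.60 against 3.39 (day 2 to 0) and 2.11 against 4.13 (day 4 to 0). HOX groups 5 to 13 gave 0.70 against 2.05 (day 2 to 0), 0.55 against 1.12 (day 3 to 2), 1.14 against 2.11 (day 4 to 2) and 1.46 against 3.28 (day 4 to 0). Stress response gave 0.36 against 0.48 (day 2 to 0, no longer apart). By construction a larger pseudocount pulls the ratios of low genes toward 0, and apart from that the cause was not tested.

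Without the filter, members under 1 CPM in both libraries enter each median. Primitive streak gave -1.35 against -1.70 (day 4 to 3) and 1.56 against 3.13 (day 4 to 0). Paraxial mesoderm gave 0.26 against 1.86 (day 2 to 0, no longer apart), 0.35 against 1.17 (day 3 to 2, no longer apart) and 0.14 against 1.34 (day 4 to 2, no longer apart). Endothelial gave 2.09 against 2.74 (day 4 to 2). Blood cell gave 0.59 against 0.73 (day 4 to 0, now apart). Definitive endoderm gave 1.66 against 2.76 (day 2 to 0). Neuroectoderm gave -0.30 against -0.91 (day 3 to 2) and -0.29 against -1.17 (day 4 to 2, no longer apart). Trophoblast and amnion gave 0.84 against 2.03 (day 2 to 0), 0.25 against 0.67 (day 3 to 2, no longer apart) and 1.10 against 2.42 (day 4 to 0). Smooth muscle and fibroblast gave 0.38 against 0.13 (day 4 to 2, now apart). NOTCH pathway gave 0.23 against 0.33 (day 3 to 2, no longer apart). Anterior HOX gave 1.26 against 3.39 (day 2 to 0), 0.57 against 1.44 (day 3 to 2), 0.34 against 1.75 (day 4 to 2, no longer apart) and 0.79 against 4.13 (day 4 to 0). HOX groups 5 to 13 gave 1.08 against 2.11 (day 4 to 2) and 2.26 against 3.28 (day 4 to 0). Replication-dependent histones gave -0.48 against -0.39 (day 3 to 2, now apart) and -0.44 against -0.52 (day 4 to 2, now apart). The added members have ratios within 1 of 0 by construction, and beyond that the cause was not tested.

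With a minimum of 5 CPM, fewer members enter each median. Pluripotency gave -0.31 against -0.11 (day 3 to 2, now apart). Primitive streak gave -0.59 against -0.96 (day 3 to 2). Paraxial mesoderm gave 1.86 against 1.86 (day 2 to 0, no longer apart), 0.85 against 1.17 (day 3 to 2, no longer apart), -0.91 against -0.21 (day 4 to 3, now apart) and -1.08 against 1.34 (day 4 to 2, reversed). Haemato-endothelial factors gave 0.83 against 0.97 (day 2 to 0, no longer apart) and 2.65 against 1.19 (day 3 to 2). Endothelial gave 0.88 against 0.29 (day 2 to 0, now apart). Definitive endoderm gave 3.68 against 2.76 (day 2 to 0). Neuroectoderm gave -1.22 against -0.37 (day 4 to 3, now apart), -2.24 against -1.17 (day 4 to 2) and -2.05 against -0.61 (day 4 to 0, now apart). Trophoblast and amnion gave 4.44 against 2.03 (day 2 to 0) and 4.71 against 2.42 (day 4 to 0). BMP targets gave 3.62 against 3.16 (day 2 to 0). NODAL and activin targets gave 1.63 against 1.10 (day 2 to 0) and -0.31 against -0.44 (day 4 to 3, no longer apart). WNT targets gave 3.28 against 2.59 (day 2 to 0). NOTCH pathway gave 0.43 against 1.0 (day 4 to 0, no longer apart). HOX groups 5 to 13 gave 3.41 against 2.05 (day 2 to 0) and 4.10 against 3.28 (day 4 to 0). A different membership is the construction of this setting, and beyond it the cause was not tested.

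On the deposited FPKM, an alternative chosen after seeing the data, these medians moved. Primitive streak gave 3.81 against 4.58 (day 2 to 0). Lateral plate and cardiac mesoderm gave 2.98 against 4.18 (day 2 to 0) and 3.76 against 4.80 (day 4 to 0). Paraxial mesoderm gave 0.67 against 1.17 (day 3 to 2, no longer apart), 0.79 against 1.34 (day 4 to 2, no longer apart) and 0.23 against 1.58 (day 4 to 0, no longer apart). Haemato-endothelial factors gave 1.98 against 2.64 (day 4 to 2). Endothelial gave 0.64 against 0.29 (day 2 to 0, now apart). Blood cell gave 0.49 against 0.10 (day 4 to 3, now apart). Definitive endoderm gave 2.02 against 2.76 (day 2 to 0), 1.49 against 1.97 (day 4 to 2) and 3.24 against 4.37 (day 4 to 0). Neuroectoderm gave -1.13 against -0.37 (day 4 to 3, now apart), -2.07 against -1.17 (day 4 to 2) and -1.66 against -0.61 (day 4 to 0, now apart). Mesenchymal gave -0.16 against -0.17 (day 4 to 3, now apart). BMP targets gave 3.11 against 3.65 (day 4 to 0). NODAL and activin targets gave -0.53 against -0.55 (day 4 to 0, no longer apart). WNT targets gave 1.71 against 2.44 (day 4 to 0). Anterior HOX gave 2.14 against 3.39 (day 2 to 0). HOX groups 5 to 13 gave 2.37 against 3.28 (day 4 to 0). Hypoxia and glycolysis gave 0.27 against 0.28 (day 4 to 3, no longer apart). Cholesterol synthesis gave 0.26 against 0.32 (day 2 to 0, now apart) and 0.24 against 0.22 (day 4 to 2, no longer apart). Replication-dependent histones gave -0.63 against -0.52 (day 4 to 2, now apart). For these medians the cause was not tested.

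Leaving out the member with the largest change moved these medians. Paraxial mesoderm gave 0.73 against 1.17 (day 3 to 2, no longer apart). Endothelial gave 2.42 against 2.74 (day 4 to 2). Neuroectoderm gave 0.90 against 0.39 (day 2 to 0, now apart) and -0.64 against -1.17 (day 4 to 2, no longer apart). Smooth muscle and fibroblast gave 0.040 against 0.28 (day 3 to 2, no longer apart). NODAL and activin targets gave 0.58 against 1.10 (day 2 to 0, no longer apart) and -0.31 against -0.44 (day 4 to 3, no longer apart). FGF and ERK targets gave -0.23 against -0.26 (day 4 to 3, no longer apart). NOTCH pathway gave 0.23 against 0.33 (day 3 to 2, no longer apart). The loss of 1 gene is the construction of this setting, and beyond it the cause was not tested.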

Other observations

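The tests of shared reads and of library scaling, and the medians without the filter, below were chosen after the result was seen. The genes in this paragraph were also chosen after their values were seen. Genes of the VEGF receptors were present before VEGF was added: at days 0, 2, 3 and 4 FLT1 measured 231, 162, 840.1 and 1091 CPM, KDR 209, 354, 868 and 942 CPM, and FLT4 8.92, 3.92, 6.18 and 16.9 CPM. The ligand gene VEGFA measured 30.6, 38.8, 35.8 and 51.6 CPM, and the angiopoietin receptor gene TEK 33.4, 35.3, 99.5 and 147 CPM. The apelin receptor gene APLNR stood at 3.30, 789, 1055 and 721 CPM, and its ligand gene APLN was also highest on day 3, at 37.3 CPM. ETV2, a regulator of early blood and vessel cells, measured 0.388, 1.37, 13.9 and 6.72 CPM, and the embryonic globin gene HBE1 0.909 CPM at day 4 and 0 before.

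Gene models that join 2 neighbouring genes were at least 4-fold different between days 4 and 3 more often than other genes under 1 of 2 definitions, and the excess varied between comparisons. A first definition, which also took synonyms, held 577 models, of which 456 were antisense RNAs, and gave a ratio of 1.73 (0.751 to 3.38) between days 4 and 3, with 8 of 381 models at least 4-fold different. The definition was narrowed to 102 models after that value was seen, and then 8 of 81 (9.88%) differed, against 1.05% of other genes in the same expression bins, a ratio of 9.39 (4.14 to 17.6), beside 6.91 between days 3 and 2, 3.94 between days 4 and 2, 2.31 between days 2 and 0, and 1.5 (0.849 to 2.36) between days 4 and 0. Family sums at days 0, 2, 3 and 4 were 349.7, 287, 222 and 361 CPM for NME1 and NME2, 147, 102, 73.1 and 67.1 for PHOSPHO2 and KLHL23, 119.7, 128, 111 and 117 for TGIF2 and RAB5IF, 69.4, 67.9, 66.3 and 63.6 for ARPIN and AP3S2, each with the joined model, 41.5, 22.2, 24.0 and 25.3 for SERF1A and SERF1B, and 51.2, 7.06, 1.16 and 0.363 for CKMT1A and CKMT1B. Whether shared reads account for the excess therefore stays open, they do not account for the lower sums of CKMT1A with CKMT1B and PHOSPHO2 with KLHL23, and no biological explanation was tested.

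Transcripts typical of liver and yolk sac, such as APOA1 and APOB, were higher at day 4, and RNA of liver cells would bring their abundant transcripts, but ALB had 2 counts at day 4, with an upper limit of 1.65% of APOA1, SERPINA1 and AHSG had 0, and TF measured 0.545 CPM. The endoderm list median ranged over 0.0146 between 3 scalings, but these moved the median of all genes by only 0.0291, so that comparison decides nothing about scaling. A second endoderm list, written before it was tested, had a median of 1.11 between days 4 and 2 against -0.45 to 0.58 in random lists, over 10 of 17 members, of which 5 were at least 2-fold higher, among them VTN, at least 21.9-fold, and FGB, 10.7-fold. FGB stood at 4.07 CPM already at day 0. FGA, also a fibrinogen gene, had no counts at day 2 and 5.63 CPM at day 4. SERPINA1, TF, AHSG, RBP4, AMN and the fibrinogen gene FGG are members too but stayed below 1 CPM on days 2 and 4. Without that filter the median was 0.77 over 15 members against -0.35 to 0.39. As a hypothesis, endoderm-type cells may have arisen in the culture, and other sources that lack ALB stay open.

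Of 20 interferon-stimulated genes of at least 1 CPM, 9 were at least 2-fold higher at day 4 than at day 3, such as IFIT1 at 46.2 against 4.45 CPM, ISG15 at 24.4 against 3.09 and IFIT3 at 19.3 against 4.45, 10 differed by less, with XAF1, HERC5 and IFI6 lower within counting error, and OAS1 was lower, at 1.27 against 4.06. Summed over the 21 other genes, without IFIT1 and DDX60 which had prompted the test, the counts were 1093 and 685, a ratio of 1.5 with an interval from 1.36 to 1.65, which argues against counting error alone. Without those 2 the median of 18 genes was 0.55 against -0.34 to 0.34 in random lists, with both it was 0.78, and without either the pair or the filter it was 0.34 over 21 genes against -0.27 to 0.25. As a hypothesis, an interferon response of the culture may underlie this. With 1 library per day it stays open whether it belongs to the day or to that library.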
